A study of Mus musculus with 14 samples.

How the data were processed

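Chromatin immunoprecipitation followed by sequencing (ChIP-seq, which recovers the DNA fragments bound by a protein with an antibody and sequences them) was performed in CH12 cells, a mouse B lymphoma line. In these cells a Flag epitope and a small molecule-assisted shutoff (SMASh) tag had been knocked in at the N-terminus of Med14, a subunit of the Mediator coactivator complex, so that the protease inhibitor asunaprevir triggers loss of the protein. Per the labels, the series comprises 14 libraries, of which 10 were immunoprecipitated with 1 of 4 antibodies (Irf4, Pu1, Brd4 or SP1) and 4 were inputs. Irf4 and Pu1 were each profiled in 1 library at 0 h and 1 library at 48 h of asunaprevir. Brd4 was profiled in 1 DMSO library and 1 library at 48 h, and SP1 in 2 DMSO libraries and 2 libraries at 60 h. The 4 inputs belong to the Brd4 and SP1 experiments, 1 for each arm. Samples were grouped by their titles.

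The data analysed here are 4 merged peak lists, 1 for each antibody. Per the submitters' processing notes, CASAVA 1.8.2, Bowtie 1.1.1 and SAMtools were used and the genome build was mm9. The alignment settings, duplicate handling, peak-calling control and merging rule are not given in the sources used here. The Irf4 and Pu1 lists the authors deposited hold a position, a peak name in the style of the MACS caller and an unnamed score for each peak. The peak names in those lists run from 1 without gaps, so each was numbered as a single list. The lowest scores were 50.0 in both lists to the printed digit. Because the score's scale is not given in the sources used here, scores served only to rank or filter peaks within a list. The Brd4 and SP1 lists the authors deposited hold a chromosome, a start and an end with no score. No list overlapped itself. The smallest gap between neighbouring peaks was 101 bp for Brd4 and 1 bp for the other lists.

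Merging has 3 consequences for the values below. No list holds a value for a single library, so the read depth behind a peak is unknown, replicate error cannot be computed, and the asunaprevir and control arms cannot be set against each other. The planned comparisons between arms for SP1, Irf4, Pu1 and Brd4 were therefore not analysed here. Peak number and width also depend on the unknown settings of each call, so widths of different lists are not a measure of how far each protein spreads. The gene table at hand follows another build than mm9, and coordinates were not converted. Promoter shares, gene lists and motif content were therefore not analysed here, and regions are named by mm9 coordinates, 1-based, without gene names.

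Overlaps were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and intervals with scipy 1.17.1 and statsmodels 0.14.6. A peak was shared when at least 1 bp of it lay in a peak of the other list. Peaks on the mitochondrial chromosome were kept out of the overlaps. The overlap expected from number, width and spacing alone was taken from 1000 circular shifts of one list, with a separate random offset for each chromosome. Each chromosome was taken to run from the first start to the last end over the 4 lists. The one-sided permutation p-value was Benjamini-Hochberg adjusted over the 6 pairs; the smallest value that 1000 shifts can give is 0.000999. In the four-way overlap the Irf4, Pu1 and SP1 lists were shifted independently. For Brd4 by factor combination, overlapping Irf4, Pu1 and SP1 peaks were joined into regions and the Brd4 list was shifted. Shares carry 95% Wilson intervals and odds ratios carry 95% intervals. These intervals treat regions as independent, which neighbouring regions are not, and cover counting error over regions only. They say nothing of the spread between cultures.

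The overlap computation was tested on simulated data before use. For a simulated Irf4 list against a simulated Pu1 list, with 10, 30 and 60% of peaks placed on the other list, 9.83, 29.4 and 59.6% were recovered, over 44341, 44378 and 44612 peaks. With none placed, the fold was 0.987. Of 100 pairs of unrelated simulated lists, 4 reached a p under 0.05. These unrelated lists were much shorter than any deposited list. All simulated lists were placed at random along the genome, without the clustering of real peaks. The simulation therefore does not show how often the test errs on clustered lists.

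Apart from the mitochondrial peaks and the Brd4 domains named later, the regions named in the text follow a rule fixed before the data were examined. The rule took the 5 highest-scoring peaks of the Irf4 and Pu1 lists and the 5 widest of the Brd4 and SP1 lists. It also took the 5 windows of 50000 bp with the most peaks among windows holding all 4 factors. Score ties were broken by chromosome. Alternatives fixed at the same time were a stricter overlap (at least 50% of the narrower peak), midpoints within 250 bp, peaks set to 200 bp, the upper 50% of each list by score or, without a score, by width, lists of equal size, local shifts of 50000 to 500000 bp, and joining of peaks under 500 bp apart. Values with lists of equal size also depend on which Irf4 and Pu1 peaks were kept, so they do not isolate list length.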

Results

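Binding of 4 nuclear proteins was mapped in CH12 cells carrying degradable Med14. Irf4 is an interferon regulatory factor of B lymphocytes and plasma cells. Pu1 (PU.1) is an ETS-family factor of myeloid and B cells that recruits Irf4 to composite DNA elements. SP1 is a ubiquitous zinc-finger factor that binds GC-rich sites. Brd4 is a bromodomain coactivator that binds acetylated histones at active promoters and enhancers. Med14 is the backbone of Mediator, which relays signals from DNA-bound factors to RNA polymerase II. The design set asunaprevir-treated cells against untreated or DMSO-treated cells for each antibody. The peak lists analysed here merge the arms of each antibody, so they show where each protein was found in either arm and how these locations coincide, and give no change on asunaprevir. A location shared by 2 lists need not have been shared within the same arm. The arms also differed between antibodies, with asunaprevir for 60 h for SP1 and 48 h for the others, and 0 h or DMSO controls.

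Pu1 had the most peaks, 75698, followed by Irf4 with 45666, Brd4 with 29432 and SP1 with 21680. Pu1 peaks covered 95.02 Mb, Irf4 peaks 78.6 Mb, Brd4 peaks 36.4 Mb and SP1 peaks 13.2 Mb. SP1 peaks were the narrowest, with a median of 494 bp (quartiles 301 and 826 bp). Pu1 peaks had a median of 1057 bp (918 and 1389 bp) and Irf4 peaks a median of 1398 bp (1096 and 2027 bp). Brd4 peaks had a median of 820 bp and the broadest spread, with quartiles of 438 and 1527 bp. Of the Brd4 peaks, 627 were wider than 5000 bp, against 622 Irf4 peaks, 116 Pu1 peaks and 0 SP1 peaks. There is 1 merged list for each antibody and no replicate list, so none of these numbers has a replicate error.

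**Figure D1:**
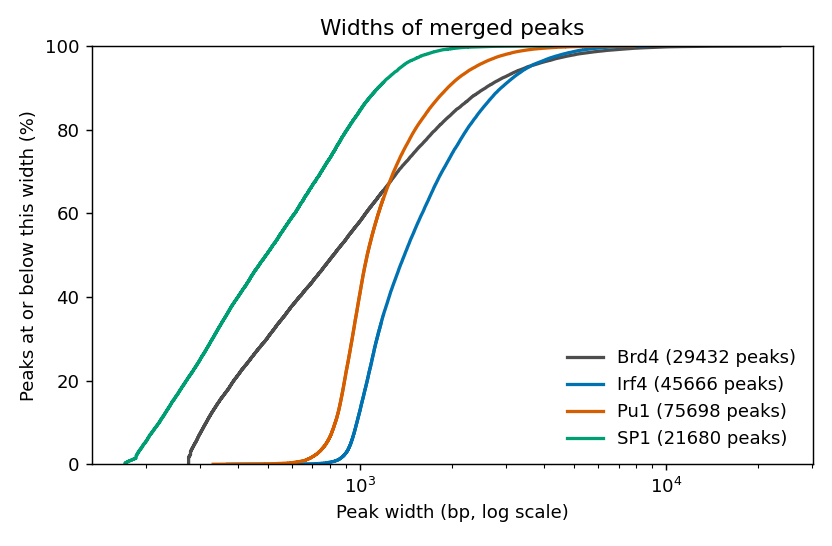
Cumulative share of peaks (%) against peak width (bp, log scale) for the 4 merged lists, 1 line for each antibody. The SP1 line lies farthest left, with a median of 494 bp, and the Brd4 line has the longest right tail, up to 23484 bp.

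The widest Brd4 peak lay on chromosome 12 from 114477181 to 114500664 and spanned 23484 bp. It held 2 Irf4 peaks, 2 Pu1 peaks and 1 SP1 peak, and further Brd4 peaks flanked it on both sides. The second, on chromosome 14 from 70452250 to 70474836, held 3 SP1 peaks, 1 Pu1 peak and 0 Irf4 peaks. The third, on chromosome 15 from 74747643 to 74768046, held 5 SP1 peaks, 2 Irf4 peaks and 2 Pu1 peaks. The fourth, on chromosome 4 from 130453765 to 130473305, held 4 SP1, 4 Pu1 and 2 Irf4 peaks. The fifth, on chromosome 10 from 43533120 to 43551952, held 3 SP1, 4 Pu1 and 2 Irf4 peaks. Among the 5 widest Brd4 peaks, the chromosome 14 peak was thus the only one without Irf4.

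**Figure D2:**
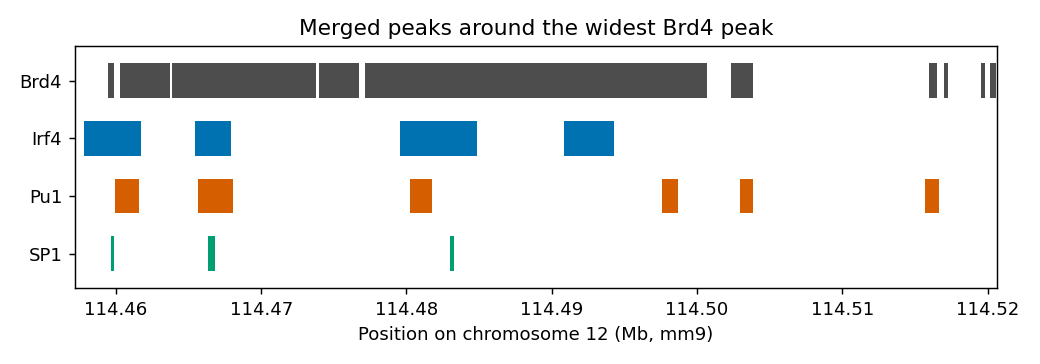
Merged peaks of Brd4, Irf4, Pu1 and SP1 (1 row each, boxes drawn to scale) around the widest Brd4 peak; the horizontal axis is the position on chromosome 12 in Mb (mm9). The Brd4 box from 114477181 to 114500664 covers 2 Irf4 peaks, 2 Pu1 peaks and 1 SP1 peak.

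The 5 widest SP1 peaks each overlapped peaks of all 3 other factors. The widest spanned 4215 bp on chromosome 5 from 109984434 to 109988648. The others lay on chromosome 7 (71081087 to 71084913), chromosome 12 (3235124 to 3238909), chromosome 14 (15177909 to 15181477) and chromosome 10 (80597717 to 80601275). The highest-scoring nuclear Irf4 peaks were tied at a score of 3100, the value of 5 peaks; the 4 named by rule were on chromosome 13 (16556543 to 16558504), chromosome 16 (55635796 to 55637996), chromosome 2 (127833605 to 127835875) and chromosome 4 (7839106 to 7841066). All 4 held a Pu1 and a Brd4 peak, and those on chromosomes 16 and 2 also held SP1. The highest-scoring Pu1 peaks were on chromosome 7 (94973005 to 94974511 and 125940882 to 125942663, both at a score of 3233), chromosome 12 (88577307 to 88578896), chromosome 8 (47680360 to 47681979) and chromosome 3 (43161641 to 43163351). Each of these 5 held an Irf4 peak. The first lacked Brd4, and only the chromosome 3 peak held SP1. The value of 3100 recurred in the Pu1 list, where 46 peaks had it and 23 exceeded it. The score's scale is unknown, so ranks at the top of either list are not shown to order binding strength.

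The densest clustering of all 4 factors was found on chromosome 13 from 23589485 to 23639484, where 50000 bp held 20 SP1, 13 Brd4, 6 Irf4 and 6 Pu1 peaks. A window on chromosome 11 from 87234763 to 87284762 held 13 SP1, 13 Brd4, 9 Irf4 and 9 Pu1 peaks. The next were on chromosome 4 (134671102 to 134721101, 38 peaks in all), chromosome 10 (79595864 to 79645863, 37 peaks) and chromosome 11 (68891436 to 68941435, 37 peaks). SP1 was the most frequent factor in 3 of these 5 windows by a margin over Brd4; the counts were equal in the first chromosome 11 window, and in the chromosome 4 window Brd4 had 13 peaks and SP1 had 11.

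The first question that the merged lists can answer is which factors were found at the same places. Of 45665 nuclear Irf4 peaks, 31589 held a Pu1 peak, or 69.2% (95% Wilson interval 68.8 to 69.6%), against 9.06% after shifting the Pu1 list, a 7.64-fold excess. The share was 47.4% when midpoints had to lie within 250 bp, 43.2% with 200 bp peaks and 49.0% with lists of equal size. In the other direction, 43.1% of the Pu1 peaks held an Irf4 peak, against 5.59% after shifts. Over 50% of the more numerous Pu1 peaks, 39534 or 52.2%, held no peak of any other factor, while this was true of 23.9% of Irf4 peaks, 17.1% of SP1 peaks and 15.0% of Brd4 peaks.

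A Brd4 peak held an Irf4 peak in 72.9% of cases (72.4 to 73.4%) and a Pu1 peak in 70.5% (70.0 to 71.1%), against 5.52 and 7.56% after shifts. These shares depend on the overlap rule, since midpoints lay within 250 bp in 37.3 and 34.6% of cases, 200 bp peaks met in 31.4 and 29.2%, and lists of equal size gave 47.6 and 35.2%. Brd4 held an SP1 peak in 44.2% of cases (43.6 to 44.8%), against 1.58% after shifts; this was 22.3% with midpoints within 250 bp, 18.2% with 200 bp peaks and 44.2% with lists of equal size. In excess over shifts Brd4 with SP1 was the highest of the 6 pairs, at 27.9-fold, compared with 13.2-fold for Brd4 with Irf4 and 9.33-fold for Brd4 with Pu1. With every list cut to 21680 peaks the folds were 27.9, 16.2 and 14.0. With every peak set to 200 bp they were 50.2, 41.8 and 23.4. The SP1 list was the shortest and its peaks the narrowest, which lowers the share after shifts and so allows a higher fold. The order of the folds is therefore not an order of how closely the factors coincide. SP1 peaks held Irf4 in 72.1%, Brd4 in 64.2% and Pu1 in 63.8% of cases, against 4.46, 2.21 and 5.82% after shifts. Of Irf4 and Pu1 peaks, 29.6 and 16.7% held SP1, whose list was the shortest. These shares were 17.7 and 9.41% with midpoints within 250 bp, 15.2 and 8.11% with 200 bp peaks, and 40.2 and 24.1% with lists of equal size. The SP1 list was not cut there, so the higher equal-size shares reflect which Irf4 and Pu1 peaks were kept. With only the upper 50% of those lists by score, chosen after seeing the data, the shares were 40.0 and 22.6%. Equal-size values therefore do not isolate list length.

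Each of the 6 overlaps exceeded all 1000 shifts (one-sided permutation test, Benjamini-Hochberg adjusted p = 0.000999 for every pair, the smallest these shifts can give). Shifts of 50000 to 500000 bp keep the density of peaks on that scale, but not clusters within shorter distances. They lowered the excess to 4.58-fold for Irf4 with Pu1, 6.96-fold for Brd4 with Irf4, 5.27-fold for Brd4 with Pu1 and 13.2-fold for Brd4 with SP1. For Irf4 with SP1 it fell from 15.0-fold to 7.71-fold and for Pu1 with SP1 from 10.5-fold to 5.81-fold. All 6 remained above every local shift.

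**Figure D3:**
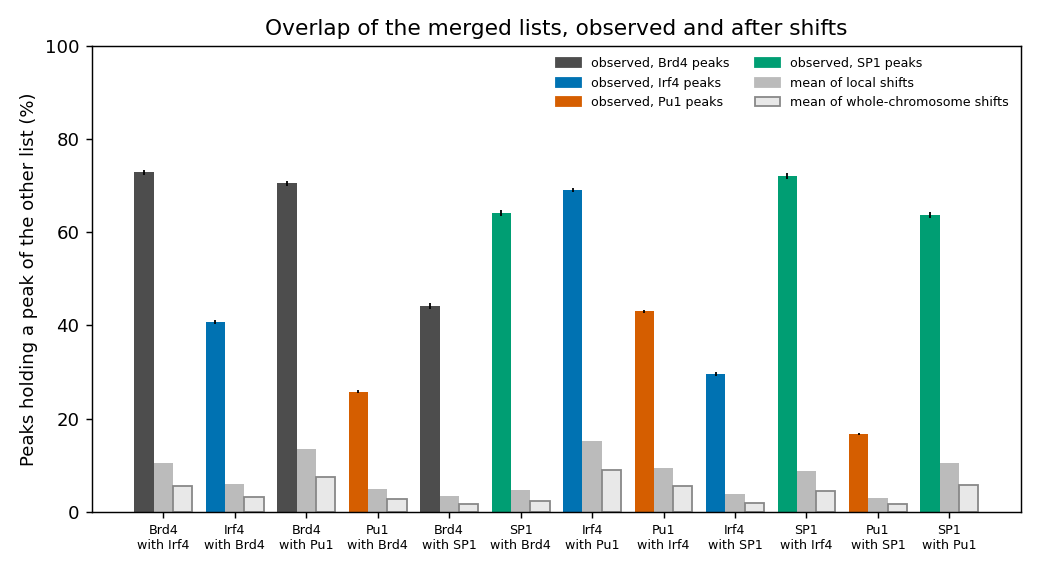
Share of peaks (%, vertical axis) of one list that hold a peak of another list, for the 12 ordered pairs on the horizontal axis. Coloured bars are observed shares with 95% Wilson intervals, and grey bars are means of 1000 local or whole-chromosome shifts; Irf4 with Pu1 stands at 69.2%, against 15.1% for local and 9.06% for whole-chromosome shifts.

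Of 29429 nuclear Brd4 peaks, 10156 held Irf4, Pu1 and SP1 together, or 34.5% (34.0 to 35.1%). With every peak set to 200 bp this fell to 1435 peaks, or 4.88%. At the deposited widths, shifting the 3 factor lists independently gave a mean of 4.87 such peaks. Shifting only the Brd4 list, which keeps the other factors together and was chosen after seeing the data, gave a mean of 292 and at most 664 (one-sided permutation p = 0.000999 in both cases, the smallest possible). Local shifts of the 3 factor lists left a 234-fold excess, against 2085-fold for whole-chromosome shifts of those lists. A further 7625 Brd4 peaks (25.9%) held Irf4 and Pu1 without SP1. Peaks with SP1 alone numbered 583 (1.98%), with Irf4 alone 2007 (6.82%) and with Pu1 alone 2370 (8.05%). The 4424 Brd4 peaks with none of the 3 factors (15.0%) were narrow, with a median of 437 bp, compared with 1210 bp for those holding all 3.

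The second question was how often Brd4 accompanied each combination of DNA-binding factors. Joining overlapping Irf4, Pu1 and SP1 peaks gave 93171 regions, of which 22270 (23.9%) held Brd4. Regions with Pu1 alone, the largest class with 41775 members, held Brd4 in 5.36% of cases (5.15 to 5.58%). Regions with Irf4 alone held it in 9.40% (8.89 to 9.93%) and regions with SP1 alone in 18.1% (17.0 to 19.3%). SP1-alone regions were the narrowest, with a median of 316 bp against 959 bp for Pu1 alone and 1099 bp for Irf4 alone. Brd4 was more frequent at SP1-alone than at Pu1-alone regions (odds ratio 3.90, 3.58 to 4.26) and at SP1-alone than at Irf4-alone regions (odds ratio 2.13, 1.94 to 2.35). The order of these shares is the reverse of list length, and lists of equal size were not run for these classes. Pu1 peaks with no other factor had a median score of 121, against 378 with all 3 others. Differences between factors here therefore cannot be told apart from differences in list length or peak score.

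Combinations held Brd4 more often than single factors. Regions with Irf4 and Pu1 held Brd4 in 32.8% of cases (32.1 to 33.4%), an odds ratio of 8.60 (8.17 to 9.06) over Pu1 alone and 4.70 (4.39 to 5.03) over Irf4 alone. Pu1 with SP1 held it in 46.5% (43.8 to 49.2%) and Irf4 with SP1 in 58.5% (56.4 to 60.6%), odds ratios of 3.93 (3.44 to 4.48) and 6.38 (5.68 to 7.16) over SP1 alone. Where all 3 factors were present, 9716 of 11489 regions held Brd4, or 84.6% (83.9 to 85.2%). This exceeded Irf4 with Pu1 by an odds ratio of 11.2 (10.6 to 11.9), Irf4 with SP1 by 3.88 (3.51 to 4.30) and Pu1 with SP1 by 6.30 (5.59 to 7.10). After shifts of the Brd4 list the shares of the 7 classes lay between 1.97 and 4.10%. The odds ratios between these classes were not adjusted for region width, list length or peak score. Median widths were 1284.5 bp for Pu1 with SP1, 1502 bp for Irf4 with Pu1, 1662 bp for Irf4 with SP1 and 2403 bp for all 3 factors.

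Regions with all 3 factors differed from regions with exactly 1 by 77.4 percentage points, against a mean of 1.56 and a maximum of 4.09 over 1000 shifts (one-sided permutation p = 0.000999, the smallest possible; odds ratio 70.8, 66.7 to 75.1). Regions with more factors were wider, with medians of 972, 1504 and 2403 bp for 1, 2 and 3 factors, and the odds ratio was 15.1 (14.1 to 16.3) within 5 equal bins of region width and 14.5 (13.6 to 15.5) with every peak set to 200 bp. Regions are not replicates, so these tests concern the merged lists and not the spread between cultures.

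**Figure D4:**
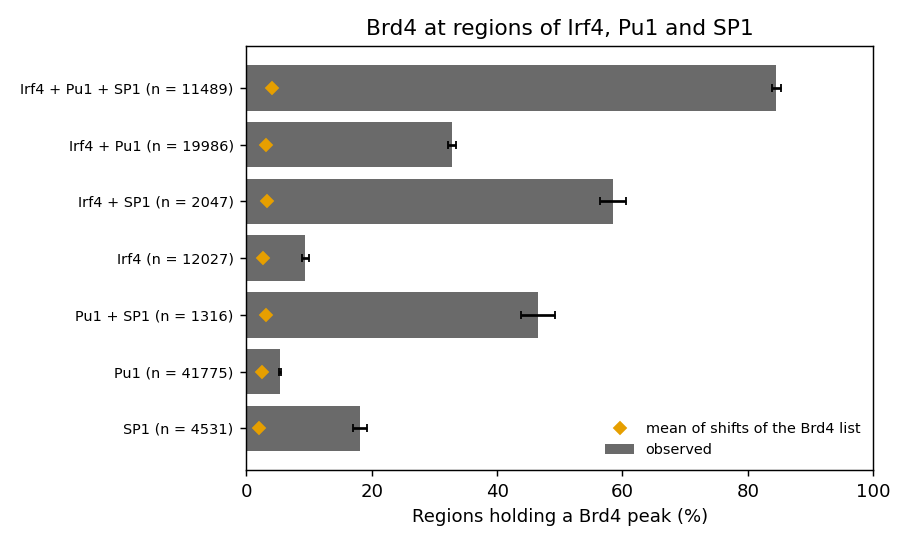
Share of regions (%, horizontal axis) holding a Brd4 peak for each combination of Irf4, Pu1 and SP1 (vertical axis, n regions). Bars are observed shares with 95% Wilson intervals and diamonds are means of 1000 shifts of the Brd4 list; the share runs from 5.36% for Pu1 alone to 84.6% for all 3 factors.

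Within the Brd4 list, wider peaks more often held the other factors. In the narrowest 5886 Brd4 peaks (276 to 388 bp), Irf4 was present in 53.6%, Pu1 in 50.5% and SP1 in 22.6%. In the widest 5886 (1768 to 23484 bp), the shares were 88.3, 89.0 and 63.1%. Shifts also raised these shares with width, from 3.86 to 9.02% for Irf4, from 4.86 to 12.9% for Pu1 and from 0.826 to 3.12% for SP1 (200 shifts). Over the 5 bins from narrowest to widest, the excess over shifts was 13.9, 15.4, 15.3, 14.3 and 9.79-fold for Irf4. It was 10.4, 11.01, 11.2, 10.2 and 6.88-fold for Pu1 and 27.4, 35.3, 35.8, 32.1 and 20.3-fold for SP1. These 5 bins are described without a test.

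Each of the Irf4 and Pu1 lists was split by score into 10 bins of equal size, bin 10 holding the highest scores. From bin 1 to bin 10 of the Irf4 list, the share of peaks holding Pu1 increased from 47.2 to 86.3%. The share holding SP1 increased from 10.2% in bin 1 to 48.9% in bin 7 and 48.8% in bin 8, and was 25.7% (95% Wilson interval 24.4 to 26.9%) in bin 10. The share holding Brd4 increased from 16.4% to 60.1% in bin 8 and was 52.5% in bin 10. The median width of the Irf4 peaks increased from 986 bp in bin 1 to 1751 bp in bin 7, and lay between 1751 and 1851 bp in bins 7 to 10. In the Pu1 list, the share with Irf4 increased from 17.1 to 87.5% and the share with Brd4 from 9.66 to 49.4%. SP1 reached 25.5% in bin 9 of the Pu1 list and was 22.5% in bin 10. The median width of the Pu1 peaks increased from 856 bp in bin 1 to 1455 bp in bin 10. Widths were not matched between bins and no shifts were run within them. Increases with score therefore cannot be told apart from increases with width. Pu1 peaks holding Irf4 had a median score of 404 (quartiles 164 and 922), against 125 (74.5 and 261) for those without. The bins were chosen after seeing the data, so no test of differences between them is reported.

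**Figure D5:**
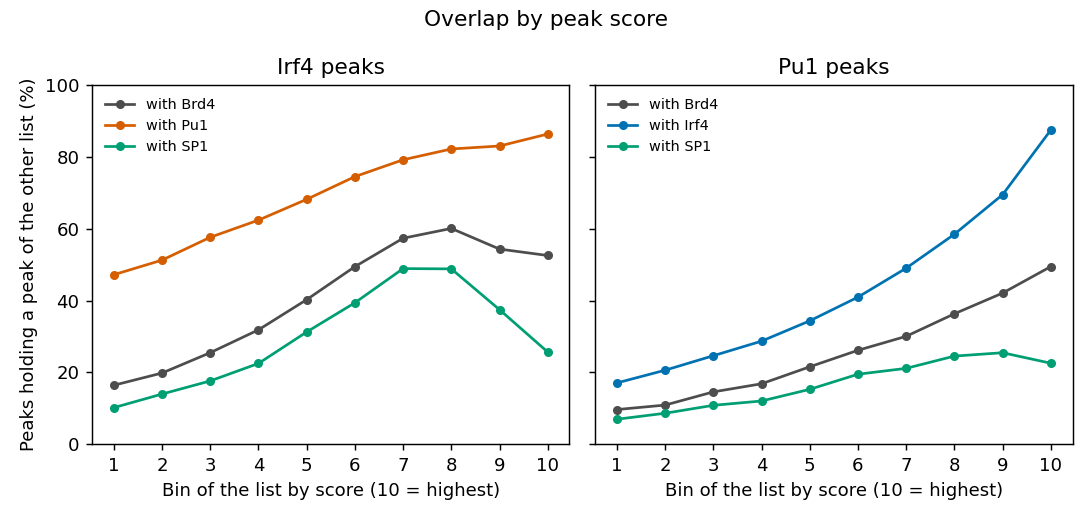
Share of Irf4 peaks (left) and Pu1 peaks (right) that hold a peak of each other factor (%, vertical axis), in equal bins of the list ordered by score (horizontal axis, 1 to 10, highest scores in bin 10). In the Irf4 list Pu1 climbs to 86.3% in bin 10, whereas SP1 stands at 48.8% in bin 8 and 25.7% in bin 10.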

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

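Of the tests in this part, the shift test of wide Irf4 peaks against Brd4, the ratio against equally wide peaks for Brd4 and the odds ratio of Brd4 within bins of region width were chosen after seeing the data.

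Peaks on the mitochondrial chromosome lay outside the comparisons. The Irf4 list holds 1 such peak, from 1 to 6586, with a score of 3143, the highest of its 45666 peaks. The Pu1 list holds 1, from 1 to 6572, with a score of 2698, which 264 nuclear Pu1 peaks exceeded. The Brd4 list holds 3, of 297 to 1167 bp, and the SP1 list holds 0. No input peak list was used, so the background level there is unknown.

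Irf4 and Pu1 peaks coincided more than shifts allow, and part of that could come from how peaks were called. Width alone is argued against as the whole cause. With every peak set to 200 bp, 43.2% of Irf4 peaks still met a Pu1 peak, above every shift, against 69.2% at the deposited width. The excess was 34.8-fold against 7.64-fold, but narrower peaks also lower the share after shifts. The higher fold therefore adds no support of its own. Shared peak density on the scale of the local shifts is argued against as the whole cause by the 4.58-fold excess over them. Local shifts do not keep clusters within shorter distances, so they cannot decide on shared neighbourhoods of that size, which stay open. Background common to these 2 lists, which have no labelled input, stays open: Irf4 peaks with Pu1 held a Brd4 or SP1 peak more often than those without (57.1 against 22.6%, odds ratio 4.57, 95% interval 4.36 to 4.78), but the peak-calling controls of those lists are not given in the sources used here and widths were not matched. Joint binding at one site is consistent with the 133.5 bp median distance between midpoints of the 32716 overlapping pairs, 0.177 of the 755 bp expected when the same widths overlap at random. Accessible chromatin that admits both proteins independently was not tested and stays open, as does the share of each arm in the merged lists.

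The higher share of Brd4 at regions with all 3 factors was tested against 2 technical explanations, region width and Pu1 score. Region width is argued against as the whole cause, since the odds ratio within 5 equal bins of width was 15.1 against 70.8 without them. The 2 narrowest bins held only 3 and 14 regions with all 3 factors. In the widest bin, with 10151 of them, the shares were 88.5 and 29.3%, and in the next, with 1254, they were 56.5 and 11.8%. Widths were not matched within bins, so how much of the difference comes from width is not settled. Stronger Pu1 peaks are argued against as the whole cause, since within 5 bins of the Pu1 score the odds ratio over Pu1 alone was 74.8 (95% interval 69.8 to 80.1) against 96.7 without them. In the lowest bin of the Pu1 score the shares were 69.7 and 2.99%. Background common to the Brd4, Irf4, Pu1 and SP1 lists could also place Brd4 peaks at regions with all 3 factors. It was not tested and stays open, because the peak-calling controls are not given in the sources used here. No biological explanation of this pattern was tested, including accessible chromatin that admits these proteins independently. Dependence on Med14 could not be tested, because the lists merge the arms with and without asunaprevir. Promoter shares, gene lists and motif content were not analysed, because the gene table at hand follows another build than mm9.

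Among the widest 1% of Irf4 peaks (over 5281 bp), 218 had a score below the list's median, and these may be diffuse background. Of these, 208 or 95.4% held a Brd4 peak, 2.36 times (95% interval 2.28 to 2.43) the 40.5% of other Irf4 peaks, all but 239 of which are narrower, so this ratio does not decide; against those 239, in the same widest 1% and of higher score, the ratio was 0.970 (95% interval 0.938 to 1.00). Contact with Brd4 by width alone is argued against, since shifts of the Brd4 list gave 7.17%, a 13.3-fold excess, whereas diffuse background that gathers at Brd4 sites stays open. A further candidate was that low scores mark broad domains with SP1, which predicts more SP1 than in those wide peaks of higher score. The ratio of shares was 0.942 (95% interval 0.861 to 1.03; 78.4 against 83.3%), so this stays open, as does an effect of the unknown peak-calling background on the score.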

How the results depend on the processing

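Each of the 51 alternative values of the overlap and Brd4 tests kept the direction and side of the threshold of the value reported. The fold over shifts ranged from 6.96 to 41.8 for Brd4 and Irf4, 5.27 to 23.4 for Brd4 and Pu1, 13.2 to 50.2 for Brd4 and SP1, 4.58 to 34.8 for Irf4 and Pu1, 7.71 to 42.2 for Irf4 and SP1, and 5.81 to 22.7 for Pu1 and SP1; local shifts gave the lowest and 200 bp peaks the highest value in each. The share of Irf4 peaks with Pu1, 69.2% in the main setting, was 47.4% with midpoints within 250 bp, 43.2% with 200 bp peaks and 49.0% with lists of equal size. Setting peaks to 200 bp lowered the Brd4 peaks with all 3 factors from 10156 to 1435, and the stricter 50% overlap gave 9041. The odds ratio of Brd4 for 3 factors over 1 ranged from 14.5 to 75.4 and was 16.8 in the upper 50% of each list. Peak numbers moved by over 1.5 times under the stricter lists, by construction: 14698 for Brd4, 22832 for Irf4, 37849 for Pu1 and 10836 for SP1. Joining peaks under 500 bp apart gave 24329, 44971, 73552 and 20122. The alternatives chosen after seeing the data were shifting only Brd4, keeping the upper 50% of only the scored lists, bins of width and leaving out chromosome X. No paired analysis was possible because the SP1 list holds no value per library; leaving out a replicate, pseudocounts, and promoter, gene list and motif settings were not run for the same reason or for lack of an mm9 annotation. The unknown read depth limits every list: a site missing from a list is not shown to be unbound.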

Other observations

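All 4 factors were densest on chromosome 11 and, among autosomes, sparsest on chromosome 3. Pu1 had 45.3 peaks per Mb on chromosome 11 and 25.9 on chromosome 3, and SP1 had 15.9 and 5.84. Chromosome X held fewer peaks per Mb than the autosomes together in every list, at 0.326 of the autosomal density for Brd4, 0.258 for Irf4, 0.263 for Pu1 and 0.288 for SP1. Joining Brd4 peaks no more than 10000 bp apart gave 15185 domains, of which 8901 were single peaks and 1041 had 5 or more. The top 1% of domains by covered bases, 151 in number, held 10.7% of all bases in nuclear Brd4 peaks. A domain on chromosome 8 from 129312505 to 129429733 had the most covered bases at this distance and held 22 Brd4, 17 Pu1, 11 Irf4 and 10 SP1 peaks. A domain on chromosome 11 from 11554814 to 11647596 came next and held 25 Brd4, 10 Pu1, 4 Irf4 and 4 SP1 peaks. A domain on chromosome 16 from 19002515 to 19068838, number 5 by covered bases, held 17 Brd4, 6 Irf4, 5 Pu1 and 0 SP1 peaks. These counts were chosen after seeing the data and carry no test.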
